A study of Mus musculus with 4 samples.

How the data were processed

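Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in endothelial cells isolated from mouse retinas at postnatal day 7. Per the labels' protocols, retinas were digested with collagenase and DNase, and endothelial cells were captured on magnetic beads carrying an antibody against the endothelial surface protein CD31. The mice carried floxed Rnf20 alleles. Those with the tamoxifen-inducible Cre recombinase driven by Pdgfb lose Rnf20 in endothelial cells, and all pups received 4-hydroxytamoxifen on each of the first postnatal days. The labels give differing statements on the number of cells used per library.

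The labels list 4 libraries. The title, genotype and merged-track name agree for 1 control library without Cre and 1 knockout library with Cre. For the other 2 libraries the title names one genotype and the genotype field and track name the other, so they were left unassigned. The labels do not say which libraries entered each group mean of the table.

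The data analysed were a single table of peaks from the authors' comparison of knockout and control, deposited as text and as a workbook. The numbers were equal in all 6891 rows, and 4 septin gene names had become dates in the text copy, so names were taken from the workbook. Coordinates are on mm10, per the submitters' processing notes. Those notes name Trimmomatic 0.36, Bowtie2, SAMtools, Picard 1.119, deepTools, MACS2, DiffBind, edgeR and ChIPseeker, without their roles, and the peak set, filters, read shifting and scaling are not given in the sources used here. The authors deposited the mean signal, the knockout level and the control level per peak as log2 values. Their log2 fold change equalled knockout minus control in all 6891 rows, within 0.011. The authors also deposited an unadjusted p-value and a false discovery rate (FDR) for each peak. All listed p-values were at or under 0.0499, so the table holds only peaks past an unadjusted threshold. Distance to the nearest transcription start site (TSS), annotation class and nearest gene are the authors' annotation, and the tool and promoter window behind it are not given in the sources used here.

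No values per library were used, so no SD, leave-one-out result or new test of single peaks could be computed. The depth per library is not given in the sources used here. The number of peaks tested, implied by FDR times rank divided by p over the 1000 smallest p-values, was about 76300. About 3800 of them would fall under p 0.05 with no effect. Counts adjusted over a gene list alone were not computed, since peaks above that threshold are not in the table. Group means bottomed out at 0.13 in the knockout column and at 0 in the control column. A fold against such a value depends on that floor, and no fold is given against a control listed at 0.

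Main results used peaks at FDR < 0.05. The shares of higher and lower peaks per annotation class, chromosome and gene list were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Lists with fewer than 5 peaks were given as counts. Medians of distance, width and mean signal were compared by two-sided permutation tests with 100000 resamples, by exact enumeration where a group held fewer than 10 peaks. Whether a gene's peaks went 1 way was compared with 10000 shuffles of direction, one-sided. These tests treat peaks as independent, which neighbouring peaks are not, and they describe the listed peaks, not the spread between animals.

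The 11 pathway lists (Notch signalling, VEGF signalling, tip cell, arterial, venous, Wnt and blood-retina barrier, pan-endothelial, TGF-beta and BMP signalling, cell cycle, extracellular matrix and adhesion, histone H2B ubiquitination and Paf1 complex) were written before the data were examined. So were the 10 cell type lists (photoreceptor, bipolar, amacrine and horizontal, ganglion, Müller glia and progenitor, astrocyte, pericyte and smooth muscle, microglia and macrophage, erythroid, pigment epithelium). Named genes followed a rule of the same date, except those said to be picked after their values were seen and the genes that hold a peak assigned elsewhere. It takes, per direction, the genes at the 10 peaks of smallest FDR and the 10 of largest absolute fold at FDR < 0.05, skipping predicted genes. It adds up to 4 genes of smallest FDR per list and 14 genes of the VEGF, Notch and RNF20 pathways. Of 4992 distinct gene symbols, 4985 matched the RefSeq gene table of assembly GRCm38.p6, the build also called mm10. That table gave the gene holding each annotated transcript.

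Settings planned at the same time were FDR < 0.01, an absolute log2 fold of at least 1, mean signal at or above the table's median of 3.74, promoters taken as within 1 kb of a TSS, peaks within 50 kb, and 1 peak per gene. The whole list at unadjusted p < 0.05, combinations with it, and the removal of 2 regions with long rows of peaks moving alike were added after seeing the data. A planned comparison of sequence motifs was not run, because no genome sequence was used here. The list test was tested on simulated directions for the 6891 peaks, in 200 simulated sets. It called a list of the size of the matrix list set to 90% higher in 92.5% of sets, one of the size of the barrier list set to 30% higher in 64.5%, and unbiased lists in 0.294% of tests. The simulation drew each peak's direction independently and adjusted over pathway and cell type lists together, while the results adjusted them separately. It therefore gives no error rate for peaks of a gene that share a direction. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.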

Results

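The series asks how loss of RNF20, the ligase that attaches ubiquitin to histone H2B, alters open chromatin in sprouting retinal endothelium, with VEGF and Notch signalling as the pathways of interest. ATAC-seq was performed on CD31-selected endothelial cells of retinas at postnatal day 7, when the vascular plexus is still spreading. The labels give 4 libraries, of which 1 knockout and 1 control have labels that agree and 2 do not. The authors' deposited table gives 1 mean per group and no error per peak, so the knockout and control columns are reported as the authors named them, without replicate spread.

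Accessibility differed at 208 peaks at FDR < 0.05 in the authors' deposited table. In knockout cells 89 of these were higher and 119 were lower. The differences of smallest FDR lay at a kinase gene intron (Mast4), at a cluster of zinc finger gene promoters on chromosome 13 and, in the other direction, at sites assigned to Sash1, Cacng6, Mir129-1 and Mir688. Where the control mean was above 0, the 71 higher peaks had log2 folds from 0.93 to 3.44 (median 1.98) in the authors' deposited table. Where the knockout mean was above its lowest value, the 88 lower peaks had log2 folds from -1.31 to -3.72 (median -2.70) in the authors' deposited table. Higher peaks made up 42.8% of the 208 (95% Wilson interval 36.3% to 49.6%, counting error only). Among called peaks with mean signal at or above the table's median the balance was the opposite, with 45 higher and 26 lower. In the whole list of 6891 peaks at unadjusted p < 0.05, 4276 were higher and 2615 lower. About 3800 listed peaks, or 55.4% of the list, would be expected with no effect.

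**Figure D1:**
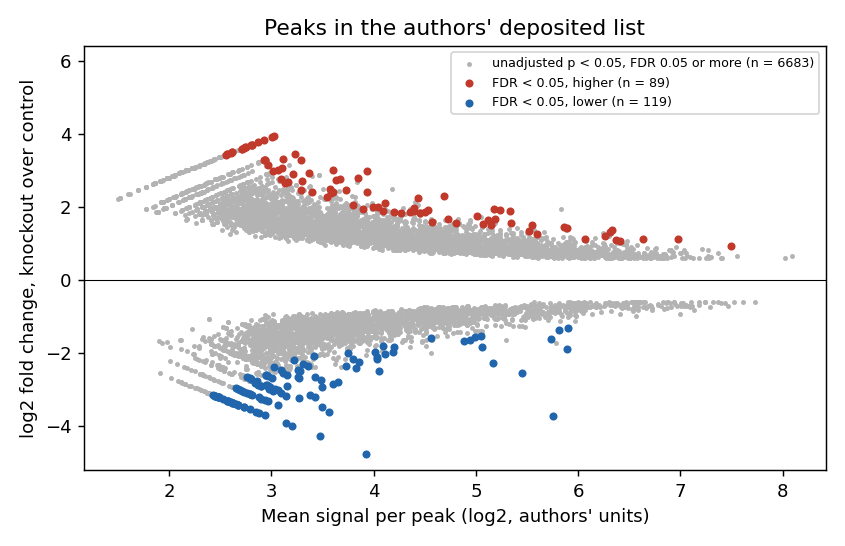
Log2 fold change, knockout over control, against mean log2 signal for the 6891 peaks of the authors' deposited table, 1 point per peak. The 89 higher and 119 lower peaks at FDR < 0.05 are coloured, and straight lines of points at low mean signal are peaks with 1 group at its lowest value.

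No peak was listed for Rnf20 itself. The gene lies on chromosome 4 from 49632005 to 49656887 (GRCm38.p6), and 0 listed peaks fell within 50 kb of it, so the table gives no accessibility readout of the targeted locus. Rnf40, which encodes its partner ligase, also had 0 listed peaks within 50 kb. Of the wider H2B ubiquitination and Paf1 list, 1 peak was called. It lay in an intron of Kmt2a, a histone H3 lysine methyltransferase gene, and was lower (log2 fold -2.59, FDR 0.0392 in the authors' deposited table). Listed but not called were introns of Dot1l, the H3 methyltransferase that acts downstream of ubiquitinated H2B (-1.35, FDR 0.153), and Usp22, an H2B deubiquitinase (-1.02, FDR 0.27, both in the authors' deposited table).

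The most significant loss of accessibility was at an intron of Mast4, a microtubule-associated kinase gene (chromosome 13, 103102558 to 103103339). There the log2 signal was 2.92 in knockout and 6.64 in control, a log2 fold of -3.72 at FDR 4.63e-16 in the authors' deposited table. Promoters of the zinc finger genes Zfp429 (-2.53, FDR 4.22e-07) and Rsl1 (-2.28, FDR 0.000255) were lower in the authors' deposited table. At the Zfp729b promoter (67609532 to 67609820) the knockout level in the authors' deposited table was 0.13, the column's lowest value, against 4.88 in control, with FDR 2.92e-07. The same floor was reached at an exon of Mansc1 (control 4.41) and in introns of Fgf12 (control 4.11) and Dlgap1 (control 3.77) in the authors' deposited table. It was also reached at an intergenic peak 175011 bases from the Foxp1 TSS (control 3.74 in the authors' deposited table). Of the 5 listed Foxp1 peaks, 2 were higher and 3 lower. Lower peaks in the authors' deposited table also included a distal site near Plk2, a polo-like kinase gene (-3.62, FDR 0.000399), and the 5' untranslated region of Ppfia4 (-2.85, FDR 0.00446). Introns of Wdr25 (-3.23, FDR 0.00527) and of Gse1, nearest to Mir7687 (-3.48, FDR 0.000399), were lower in the authors' deposited table. A peak assigned to Ptn, a heparin-binding growth factor gene, lay inside Dgki, and 1 assigned to Rprl2 inside Tbl1xr1. Both stood at the knockout floor of 0.13 in the authors' deposited table. Ptn also had 2 higher listed peaks, and Rprl2, Mast4, Plk2 and Fgf12 had 1 each. In all, 31 of the 119 lower peaks had the knockout mean at this floor.

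Of the 89 higher peaks, 52 were intergenic. The smallest FDR among them was at an intergenic peak on chromosome 10 (9239897 to 9240385) assigned to Sash1, a scaffold protein gene, with log2 signal 5.84 in knockout and 3.92 in control (1.93, FDR 0.00126 in the authors' deposited table). Peaks assigned to Cacng6 (2.30, FDR 0.0026, beside 1 lower listed peak), Mir129-1 (3.01, FDR 0.00631), Mir688 (1.46, FDR 0.00738) and Dlec1 (2.78, FDR 0.00772) were higher in the authors' deposited table. So were peaks assigned to Oasl1 (2.24, FDR 0.00885), Rgmb, a BMP co-receptor gene (2.73, FDR 0.0169), and Utp14a (1.92, FDR 0.0214), again from the authors' deposited table. S1pr1 encodes the sphingosine 1-phosphate receptor that restrains endothelial sprouting. The called peak assigned to S1pr1 (chromosome 3, 115647027 to 115647590) was intergenic, 67746 bases from its TSS. It was higher by 1.50 at FDR 0.0169 in the authors' deposited table. All 4 of its listed peaks had positive folds. The largest gains had a control mean of 0, so no fold is given. Their knockout levels in the authors' deposited table were 3.94 near Nabp1, 3.92 near Hvcn1, 3.83 near Aldoart1, 3.76 in an Adora1 intron, 3.71 near Gpr132 and 3.70 at the Evx1os promoter. A control mean of 0 was listed for 18 of the 89 higher peaks, Csmd3, Tmtc1, Rit2 and Tuba3b among them.

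Among the endothelial gene lists, called peaks were few and none of the lists was tested at this threshold. The tip cell and matrix lists held 4 called peaks between them, all higher, with the Col4a2 peak in both lists. Tip cells lead each sprout. Of 28 tip cell genes, 2 had called peaks, and all 3 of these peaks were higher, and without the region around Pdgfb, the gene on which the Cre driver is built, 1 gene and 1 peak remain. Pdgfb, the tip cell growth factor that recruits pericytes, had 2 called peaks on chromosome 15. They spanned 80025580 to 80026028 (1.32, FDR 0.0284) and 80024010 to 80024835 (0.93, FDR 0.0362 in the authors' deposited table). The authors' deposited table gives the latter a distance of -9446 bases to the TSS, while in the RefSeq table it overlaps the 5' boundary of the gene at 80024614. The third, assigned to the basement membrane collagen gene Col4a2, lay in an intron of Col4a1 (2.97, FDR 0.0368 in the authors' deposited table). The called peak assigned to Adamts9, a secreted protease gene of the matrix list, was higher (1.98, FDR 0.0214 in the authors' deposited table). That peak (chromosome 6, 93266848 to 93267274) was intergenic, at a distance of -323527 bases to the Adamts9 TSS in the authors' deposited table. Of the arterial list, the 1 called peak was near Tm4sf1, a membrane protein gene of migrating endothelium (2.10, FDR 0.0328 in the authors' deposited table). Of the barrier list, the 1 called peak was lower, near the Wnt effector Tcf7l1 (-3.24, FDR 0.0214 in the authors' deposited table). Of the pan-endothelial list, an intron peak of Fli1, an ETS transcription factor gene, was lower (-1.81, FDR 0.039 in the authors' deposited table). Of the 4 listed Fli1 peaks, 2 were higher and 2 lower. No list reached the 5 called peaks needed for a test. The venous, VEGF, TGF-beta and BMP, and cell cycle lists had 0 called peaks.

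Over the whole list at unadjusted p < 0.05, a setting added after seeing the data, 2 of the 10 pathway lists with enough peaks leaned 1 way. Peaks near matrix and adhesion genes were mostly higher, 37 of 43 (86.0%, against 61.9% of all other peaks; Fisher's exact test, odds ratio 3.80, adjusted p = 0.00384). They covered 24 genes. Folds were positive at all 4 peaks of Adamts9, and at both of Adamts1, another secreted protease gene, over 50 kb from its TSS. Itgb1 was an exception, with an intron peak at -2.60 and FDR 0.0501 in the authors' deposited table. Peaks near Wnt and blood-retina barrier genes were mostly lower, 18 of 24 (25.0% higher, against 62.2% of others; Fisher's exact test, odds ratio 0.203, adjusted p = 0.00384). They included both listed peaks of Tcf7, a Wnt effector (smallest FDR 0.146, -1.47 in the authors' deposited table). Abcb1a, the P-glycoprotein efflux pump gene, had 1 peak, inside Rundc3b, at -1.46 (FDR 0.114 in the authors' deposited table). Tspan12, a co-receptor gene of Norrin signalling, had 1 peak at 2.59 (FDR 0.19) and 1 at -0.94 (FDR 0.212) in the authors' deposited table. The higher peak lay in a Kcnd2 intron, 218147 bases from the Tspan12 TSS, and the lower in a Tspan12 intron, 1174 bases from it. With 1 peak per gene both lists had adjusted p = 0.0418. Restricted to peaks within 50 kb, the matrix list no longer passed (adjusted p = 0.156) and the barrier list did (adjusted p = 0.000976).

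Notch pathway peaks went both ways, and VEGF pathway peaks passed a test in 1 setting only. Of 34 Notch pathway genes, 1 had a called peak, which was lower. It was assigned to Ncstn, a subunit gene of the protease that releases active Notch, and lay within an intron of Copa, at 172095397 to 172096070 on chromosome 1 (-1.66, FDR 0.0284 in the authors' deposited table). At unadjusted p < 0.05, Notch peaks were 8 higher and 8 lower (50% higher, against 62.1% of other peaks; Fisher's exact test, adjusted p = 0.353). Within 50 kb of a TSS they were 4 higher and 8 lower (Fisher's exact test, adjusted p = 0.187). The ligand gene Jag1 had 2 peaks with positive and 1 with negative fold (smallest FDR 0.0702, 1.86 in the authors' deposited table). The 2 positive Jag1 peaks were intergenic, over 50 kb from its TSS, and the negative peak (-1.29) lay in a Jag1 exon. Rbpj, the Notch transcription factor gene, had 2 with positive fold (smallest FDR 0.0916, 1.42), Dlk1 1 at 2.29 (FDR 0.217), and the target Hes1 1 at 1.89 (FDR 0.26), in the authors' deposited table. The Notch1 intron peak stood at -1.03 (FDR 0.357 in the authors' deposited table). No peaks were listed for Notch4, Dll4, Hey1 or Hey2. VEGF pathway peaks were 9 higher and 14 lower (39.1% higher, against 62.1% of other peaks; Fisher's exact test, adjusted p = 0.0968). Within 50 kb of a TSS, VEGF peaks were 3 higher and 11 lower (Fisher's exact test, adjusted p = 0.0631). Vegfa and Nrp1 had 0 listed peaks. The VEGF receptor genes had uncalled peaks in the authors' deposited table, with -1.46 for Kdr (FDR 0.382) and -1.42 for Flt4 (FDR 0.501). Flt1 had 1 peak at -1.07 (FDR 0.248) and 2 at 0.81 (FDR 0.315) and 0.77 (FDR 0.479) in the authors' deposited table. Ptk2, the focal adhesion kinase gene, came closest to the threshold (-1.88, FDR 0.0589 in the authors' deposited table). With directions shuffled within annotation class, VEGF peaks were higher less often than expected (39.1% against 64.9%), as were pan-endothelial peaks (43.3% against 65.0%; permutation test, adjusted p = 0.0307 for both).

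The remaining pathway lists did not pass Fisher's exact test at unadjusted p < 0.05. Arterial peaks were 13 higher and 4 lower (adjusted p = 0.353), but 1 higher and 4 lower within 50 kb of a TSS (Fisher's exact test, adjusted p = 0.195). Of the 8 peaks assigned to Efnb2, the arterial ephrin ligand gene, 7 had positive folds (smallest FDR 0.0599, 2.29 in the authors' deposited table). Those 7 lie from 172180 to 696044 bases from the Efnb2 TSS, and the 1 within 50 kb had a fold of -1.14 in the authors' deposited table. Tip cell peaks were 19 higher and 7 lower (Fisher's exact test, adjusted p = 0.353), with Esm1 at 3 and 1 and Igfbp3 at 2 and 0. With 1 peak per gene, tip cell peaks were 7 higher and 6 lower (53.85% higher, against 59.51% of others; Fisher's exact test, adjusted p = 0.812). Venous peaks were 4 higher and 7 lower (Fisher's exact test, adjusted p = 0.231), among them 2 of the receptor gene Nrp2 with negative folds. Pan-endothelial peaks were 13 higher and 17 lower (Fisher's exact test, adjusted p = 0.0968), with 4 of 5 negative for Mef2c and 2 of 2 positive for Cdh5, the VE-cadherin gene. Both Cdh5 peaks were intergenic and over 50 kb from its TSS. TGF-beta and BMP peaks were 19 higher and 14 lower (adjusted p = 0.594), but 3 higher and 10 lower within 50 kb (Fisher's exact test, adjusted p = 0.0749), and both listed Smad1 peaks had negative folds. Cell cycle peaks were 11 higher and 13 lower (adjusted p = 0.231). Both listed Myc peaks had positive folds (1.45, FDR 0.114 for the first in the authors' deposited table), and the Ccnd1 peak was at -2.13 (FDR 0.0922 in the authors' deposited table).

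Markers of other retinal cell types were rarely near called peaks. The called peaks were a lower one assigned to the amacrine and horizontal cell regulator Foxn4 (-1.58, FDR 0.0435) and a lower one in an intron of the erythroid gene Ank1 (-2.17, FDR 0.0366 in the authors' deposited table). The Ank1 promoter also had a higher peak that was not called (2.22, FDR 0.245 in the authors' deposited table). The other 8 cell type lists had 0 called peaks. At unadjusted p < 0.05, 0 of the 9 cell type lists with at least 5 peaks passed. Amacrine and horizontal cell peaks came closest, with 1 higher and 5 lower (Fisher's exact test, adjusted p = 0.29), including the promoters of Pax6 (-1.34) and Barhl2 (-1.73) in the authors' deposited table. Counts were 8 higher and 1 lower for astrocytes, 6 and 1 for ganglion cells, 7 and 4 for photoreceptors and 8 and 5 for bipolar cells. They were 11 and 9 for Müller glia, 5 and 7 for pericytes, 5 and 2 for microglia, 1 and 2 for erythroid cells and 6 and 2 for pigment epithelium.

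Accessibility gains lay in intergenic DNA more often than losses did. Of 98 called intergenic peaks, 52 were higher (53.1%), against 33.6% of all other called peaks (Fisher's exact test, odds ratio 2.23, adjusted p = 0.0416). Called promoter peaks were 1 higher and 8 lower (Fisher's exact test, adjusted p = 0.325), the losses including Zfp429, Rsl1 and Zfp729b. Intron peaks were 35 higher and 59 lower (Fisher's exact test, adjusted p = 0.427). In the whole list 75.1% of 3009 intergenic peaks, 55.5% of 3061 intron peaks, 36.4% of 415 promoter peaks and 32.3% of 155 exon peaks were higher. Adjusted p there was 1.57e-86 for intergenic and 5.10e-27 for promoter peaks. The intergenic call at FDR < 0.05 did not pass without the 2 regions around Pdgfb and the zinc finger cluster (adjusted p = 0.18) or at an absolute log2 fold of at least 1 (adjusted p = 0.0593).

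**Figure D2:**
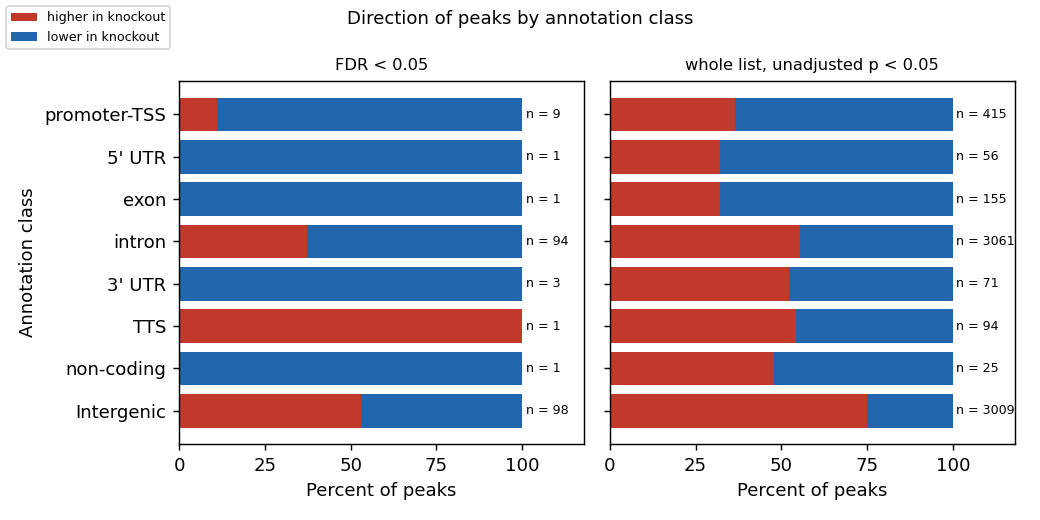
Percent of peaks higher (red) and lower (blue) in knockout per annotation class, for peaks at FDR < 0.05 (left) and the whole list (right), with the number of peaks beside each bar. Intergenic peaks are 53.1% and 75.1% higher, promoter peaks 11.1% and 36.4%.

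Called higher peaks were wider and stronger than called lower peaks. Median width was 305 bases for higher and 215 for lower peaks (permutation test, p = 9e-05). Median mean log2 signal was 3.80 and 3.01 (permutation test, p = 1e-05, the smallest the resamples can give). Median distance to the TSS was 31179 bases for higher and 21583 for lower peaks, which did not pass (permutation test, p = 0.297). At mean signal at or above the table's median the widths were 461 and 464 bases. At FDR < 0.01 neither the width nor the signal difference passed. In the whole list mean log2 signal differed by 0.07 (permutation test, p = 0.0529).

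Called peaks on chromosomes 13 and X went mostly 1 way each, but neither chromosome passed at FDR < 0.05. On chromosome 13, 14 of 16 called peaks were lower, including those of Mast4, Plk2, the sphingosine receptor gene S1pr3 and 6 at the zinc finger cluster (Fisher's exact test, adjusted p = 0.155 over 20 chromosomes). Among called peaks with mean signal at or above the median chromosome 13 did pass, with a share of higher peaks that differed from other chromosomes by -59.86 points (Fisher's exact test, adjusted p = 0.0178). That setting includes peaks of the zinc finger cluster. Without the regions around Pdgfb and the cluster, and with no signal limit, the difference was -24.74 points (Fisher's exact test, adjusted p = 0.8597). On chromosome X all 6 called peaks were higher, near Utp14a and the cohesin gene Stag2 among others (Fisher's exact test, adjusted p = 0.111). Both listed chromosome Y peaks had negative folds, and the sex of the pups in each group is not given in the sources used here. S1pr3 and Stag2 were picked after their values were seen. At unadjusted p < 0.05, genes with several peaks tended to move 1 way. All peaks of 748 of 1310 such genes had the same sign (57.1%, against 44.6% in shuffles; one-sided permutation p = 0.0001, the smallest the shuffles can give). These shuffles ignored annotation class, which peaks of a gene can share. Of 382 genes with 3 or more peaks, 144 had only higher and 25 only lower peaks. With 62.05% of listed peaks higher, an excess of genes with only higher peaks is expected, and its size was not computed. At FDR < 0.05, 3 genes had 2 or more peaks and 2 of them moved 1 way, which did not pass (one-sided permutation p = 0.518). Without the regions around Pdgfb and the zinc finger cluster, 0 of 1 such gene did.

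**Figure D3:**
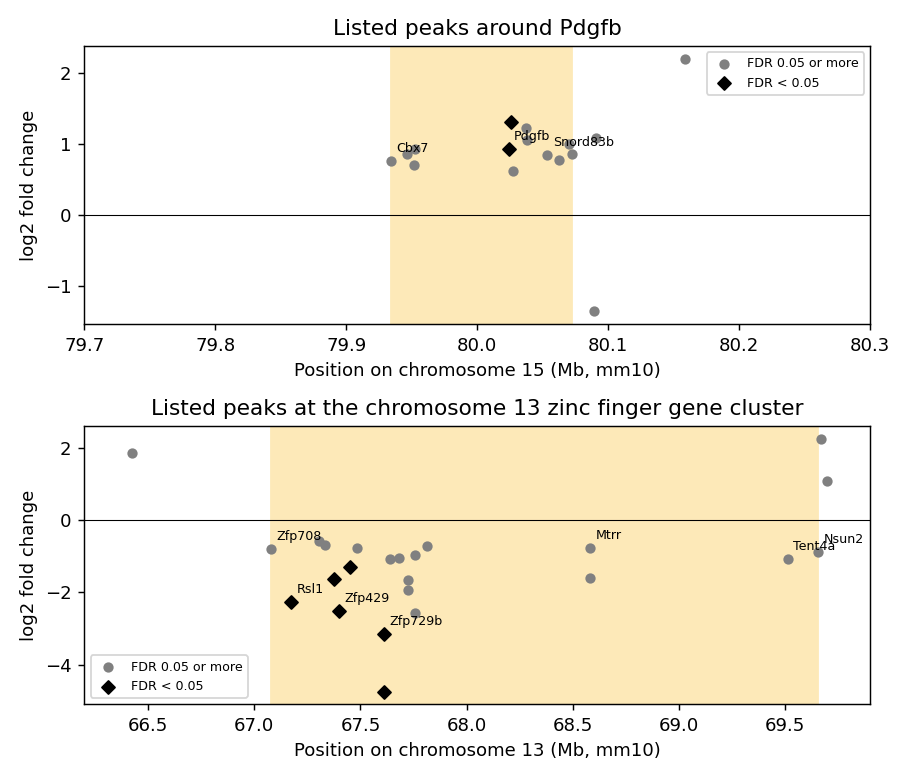
Log2 fold change of each listed peak against position around Pdgfb (chromosome 15) and at the zinc finger gene cluster (chromosome 13), on mm10, with diamonds for FDR < 0.05 and shading over consecutive peaks of 1 direction. The shaded rows hold 13 higher and 21 lower peaks.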

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

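The settings at unadjusted p < 0.05 or without the 2 clustered regions were chosen only after the results were seen, and the others were planned. Of 54 alternatives with a test in both settings, 33 kept the direction and the side of the threshold, 13 newly passed it, 5 no longer did and 3 turned the direction. The other 71 are counts, shares or lists untested in 1 or both settings and say nothing on calls. The cause was not tested except where a setting leaves fewer peaks.

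At FDR < 0.01, 7 peaks were higher and 15 lower (31.82% higher), with fewer peaks by construction; the median differences in width (63 bases) and mean signal (0.87) did not pass. At mean signal at or above the median, 45 were higher and 26 lower (63.38% higher), and the width difference was -3 bases. Promoters then differed from other peaks by -67.16 percentage points and chromosome 13 from the other chromosomes by -59.86, both past the threshold. Both comparisons include called peaks of the zinc finger cluster, such as Rsl1 and Zfp429. Neither was run at this signal limit without the cluster. At an absolute log2 fold of at least 1 the intergenic difference was 18.94 points and did not pass, and that of genes with several peaks was -1.185 points, from 2 genes. With promoters taken within 1 kb the promoter difference was -38.22 points and passed. Called peaks within 1 kb of a TSS also include those of the zinc finger cluster, and this setting was not run without the cluster.

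At unadjusted p < 0.05, 4276 peaks were higher and 2615 lower (62.05% higher). Promoters then differed by -27.31 points (-35.28 within 1 kb), introns by -11.84, distance to the TSS by 18039 bases (14832 with 1 peak per gene), mean signal by 0.07, which did not pass, and genes with several peaks by 12.5 points. With mean signal at or above the median as well, 2187 were higher and 1275 lower (63.17%), promoters differed by -35.84 points, introns by -15.55, distance by 24318 bases and genes with several peaks by 20 points. Of the pathway lists, 2 passed at unadjusted p < 0.05, 2 with the signal limit, 1 within 50 kb, 2 with 1 peak per gene and 4 with directions shuffled within annotation class. Without the 2 clustered regions the intergenic difference was 16.51 points and that of genes with several peaks -50.46, from 1 gene. The promoter difference was then -24.1 points and that of chromosome 13 -24.74. None of these passed. Promoters and chromosome 13 had not passed at FDR < 0.05 with the regions kept either.

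No paired analysis was possible because the table gives 1 mean per group. For the same reason leaving out a library was not run, and depth per library, which limits calls at weak peaks, is not known here. Sequence features were not compared. Chromosome X at FDR < 0.01 and lists with fewer than 5 peaks gave no tested value.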

Other observations

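Many genes outside the lists had several listed peaks wholly or mostly of 1 sign. The examples here were picked after their values were seen, stand for no tested group, and had no peak at FDR < 0.05. All 7 listed peaks assigned to Zfp462, a zinc finger gene, had positive folds (median log2 fold 1.57, smallest FDR 0.0839). So had all 6 peaks assigned to Tns3, an integrin adaptor gene (median 1.47), 4 of them in its introns, and all 5 of the adenosine kinase gene Adk, all in its introns. The 6 peaks assigned to the semaphorin receptor gene Plxna1 (median 1.31) were also positive but lie in introns of Chchd6, over 50 kb from the Plxna1 TSS. Those assigned to Marcks, an actin-binding protein gene (6, median 1.06), and to the potassium channel gene Kcnj2 (5) were positive and intergenic, again over 50 kb away. Foxo1, a transcription factor gene of vascular growth, had 1 peak with positive and 4 with negative fold (median -1.21, smallest FDR 0.348), and Pard3, a polarity gene, had 2 and 4 (median -1.30). On chromosome Y, the 2 listed peaks had negative folds in the authors' deposited table, at the Eif2s3y promoter (-1.53, FDR 0.282) and near 1700020D14Rik (FDR 0.259).

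All tests of the 3 patterns that follow were chosen after the results were seen. The 2 regions were also defined after looking, the one at Pdgfb with gaps under 100 kb between peaks and the one on chromosome 13 with no limit on gaps. An explanation confined to Pdgfb itself was set aside once the neighbouring peaks were seen to have positive folds as well.

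Around Pdgfb, 13 neighbouring listed peaks (15:79933780-80072503; 5 assigned to Pdgfb, 4 to Cbx7 and 4 to Snord83b) all had positive folds, 2 of them at FDR < 0.05, with a median log2 fold of 0.87. Shuffled directions gave a stretch as long in 40 of 10000 shuffles (permutation p = 0.0041). This cannot exclude unlinked directions, since shuffling ignored annotation class and that neighbouring peaks go together. The authors annotated all 13 peaks as intergenic. By RefSeq coordinates, however, the called peak at 80024010 to 80024835 overlaps the 5' boundary of Pdgfb. In the whole list 75.1% of peaks annotated as intergenic were higher, against 62.05% of all peaks. Knockout mice carry a driver built on Pdgfb, so extra copies of this DNA could raise reads across it alike; the SD of the folds (0.197) was no smaller than in many matched sets of higher peaks (34.08% at or under it), which leaves this open. The Pdgfb peaks had a median of 1.07 against 0.855 for the others (exact permutation p = 0.02409). The region was taken as the longest row of neighbouring higher peaks, not for its Pdgfb calls. But this comparison was chosen after the called Pdgfb peaks were seen, so it decides nothing on a regulatory change that is strongest there. The labels do not state what DNA the driver carries, so the higher Pdgfb peaks may reflect the transgene, the loss of RNF20 or both.

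On chromosome 13 (67081026-69655808), 21 consecutive listed peaks all had negative folds, 6 at FDR < 0.05 and 17 assigned to Rsl1 and other zinc finger genes, followed by Mtrr, Fastkd3, Tent4a and Nsun2. None of 10000 shuffles gave a stretch as long (permutation p = 0.0001, the smallest they can give). These shuffles also ignored annotation class. Of the 21 peaks, 12 were promoter peaks, a class of which 36.4% were higher in the whole list. A change at zinc finger promoters as a class stays open, since off chromosome 13 Zfp promoters were lower at 9 of 11 listed peaks against 236 of 381 for other promoters (Fisher's exact test, p = 0.2211). Of these 11, 0 were at FDR < 0.05, but only 9 of all 415 listed promoter peaks were, so this count decides little. A strain haplotype carried along most of chromosome 13 cannot be told apart either, because called peaks outside the cluster had an odds ratio of 1.115 (95% interval 0.593 to 2.10) against other chromosomes. A haplotype confined to the cluster and reads shared between these paralogs were not tested, so the zinc finger genes could differ for reasons other than RNF20.

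In the whole list, promoter peaks were higher less often than intergenic peaks (odds ratio 0.190, 95% interval 0.153 to 0.236). Within deciles of mean signal the odds ratio was 0.1855, and within deciles of width 0.1834, which argues against a difference in either as the whole cause. Beyond 5 kb from a TSS, intron and exon peaks were also higher less often than intergenic peaks at the same distance (0.5244, 95% interval 0.466 to 0.590). A shift of peaks inside genes needs this, but the class shares were known when the comparison was chosen. It adds only that the difference remained within distance deciles. In the whole list both intron peaks (55.5% against 67.3% of other peaks) and exon peaks (32.3% against 62.7%) were higher less often, which is a relative shift. A difference in signal-to-noise between libraries was not tested, since no values per library were used, so no biological claim follows.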
